A study of Solanum lycopersicum with 36 samples.

How the data were processed

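Root RNA of tomato (Solanum lycopersicum) was measured on 36 Affymetrix tomato arrays, with 3 arrays, labelled as biological replicates, in each of 12 groups. The groups cross 2 lines (wild type cv. Pearson, WT, and the ethylene-insensitive line never ripe, NR), 2 watering regimes (well-watered, WW, watered to 100% of the substrate's water-holding capacity, and drought, D, watered to 60%) and 3 inoculations (none, NO; Bacillus megaterium, BM; Enterobacter C7, C7). Plants were sampled 8 weeks after inoculation. Group names join these codes, so that WT_BM_D is wild type with Bacillus megaterium under drought. The groups were taken from the sample labels and were never changed from the values.

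The deposited values are on a log2 scale, as their range of 0.205 to 12.7 shows, and were normalized between arrays and summarised per probe set by the authors. Array medians over all probe sets, controls included, lay between 5.56 and 5.64. The submitters' processing notes name limma, without a version, and R 3.2.2. The methods of background correction, normalization and summarisation are not given in the sources used here. Of the 10209 probe sets on the array, 171 control probe sets were left out of the tests and 10038 were tested, with no filter on low values. Only 909 probe sets carry a gene identifier in the array annotation used here, for 803 genes, and 9129 do not. Statements on named genes and gene groups therefore cover a small part of the array. Gene positions are those of assembly SLM_r2.1, in which 786 of the 803 genes are current.

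Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group over all 36 arrays, no block). In all, 26 contrasts of group means were tested. These were each strain against no inoculation and the strains against each other within every line and regime, NR against WT within each regime and D against WW within each line in non-inoculated plants, the averages of these effects over all groups, and 5 interactions. P-values were adjusted by Benjamini-Hochberg over all probe sets within a contrast, with 0.05 as the threshold. The p-values rest on the spread between arrays of a group, and the number of arrays limits the precision. A log2 change is given with its standard error (SE), and fold is 2 to that power.

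Genes were named by a rule that used only the test results. It took up to 10 higher and 10 lower genes per average contrast by size of change among those past the threshold. For a contrast of 3 arrays against 3 it took up to 6 each way whose groups did not overlap, and chance alone separates 3 against 3 values for 10% of probe sets. It further took up to 4 members of each gene list past the threshold and the 2 genes of lowest p where none passed. ETR3, the receptor gene known from the never ripe line, was always included. A gene with several probe sets was represented by the one with the highest mean. Probe sets named outside this rule are said to be so where they appear.

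Gene lists were tested with camera from limma, on 1 probe set per gene, with its preset correlation and again with an estimated correlation, and were adjusted over the lists within a contrast. The 22 lists cover ethylene biosynthesis, ethylene perception and signalling, ethylene response factors, ethylene-responsive cDNAs, abscisic acid with dehydration and osmolytes, pathogenesis-related proteins, jasmonate and wounding, WRKY factors, auxin, gibberellin with cytokinin and brassinosteroid, phenylpropanoids and flavonoids, antioxidant enzymes, heat shock proteins and chaperones, nitrogen, phosphate, iron and metals, cell wall modification, photosynthesis in green tissue, cytosolic ribosomal proteins, cell cycle and histones, terpenoids and carotenoids, and sugars. The themes were fixed in advance, but membership had to be written from gene symbols, since the annotation holds no descriptions. This was done after the symbols were seen and before any test. Some themes were merged and 2 lists (ethylene-responsive cDNAs and sugars) were added at that point.

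The procedure was tested on simulated data for 3 comparisons, in which 200 of 10038 probe sets were shifted. Values were drawn independently from normal distributions with each probe set's mean and fitted spread. At a log2 change of 1, limma recovered 159 with 13 false calls for 3 arrays against 3. It recovered 190 with 11 false calls for the average over lines, and 189 with 13 false calls for the average over BM. At a log2 change of 2 it recovered 183 with 4, 200 with 12 and 199 with 10 false calls. A shifted gene list was called in the simulation and 0 other lists were. The simulated arrays hold no labelling level, no correlation between genes and no atypical arrays. False calls in the measured arrays from such structure are therefore not covered.

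Replicate numbers were tested for pairing of the samples. In 1 of 16 single contrasts did all 3 arrays of equal number correlate above 0.1, so the numbers were not used as a block in the values reported.

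Alternatives fixed before the data were examined were quantile normalization, removal of the dimmest 25% of probe sets, the replicate number as a block, array weights, a fit to the groups of the contrast alone, leaving out each array in turn, an estimated correlation for the lists and all probe sets of the listed genes. Chosen after seeing the data were a fit without the 2 nearly identical arrays, a fit without 5 doubted arrays, the 3' minus 5' signal of control genes as a covariate, and the labelling level as a random block or as a term in an additive model of line, regime and inoculation. Also added then were marker probe sets chosen without the arrays of low labelling level and a drought comparison with each of 6 arrays left out. The labelling level is the mean of the 24 poly-A control probe sets, which report RNA added before labelling. It was called low under 5, high over 8 and middle between them on the log2 scale. The labels give no hybridisation date, so none was used. Probe-level intensities were not used here.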

Results

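Roots of tomato plants were profiled on 36 arrays, labelled as 3 biological replicates per group. Wild type plants (WT) and never ripe plants (NR), which are insensitive to the gas hormone ethylene, were compared with and without inoculation by 1 of 2 bacterial strains and with full or reduced water. Each line and regime holds 9 arrays, and each of the 12 groups holds 3. Array medians over all probe sets, controls included, ranged from 5.56 to 5.64 on the log2 scale.

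Control signals differed between groups. The poly-A controls averaged 9.68 (SD 0.28, n = 9) in well-watered NR, 7.14 (SD 1.64) in NR under drought, 5.36 (SD 1.37) in well-watered WT and 3.76 (SD 0.34) in WT under drought. By this level 12 arrays were low, 13 middle and 11 high. All low arrays carried the WT label and all high arrays the NR label. The 3' minus 5' signal of control genes, a sign of RNA quality, averaged 2.52 (SD 0.28) in well-watered NR, 2.06 (SD 0.35) in NR under drought, 1.92 (SD 0.20) in well-watered WT and 1.84 (SD 0.27) in WT under drought.

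**Figure D1:**
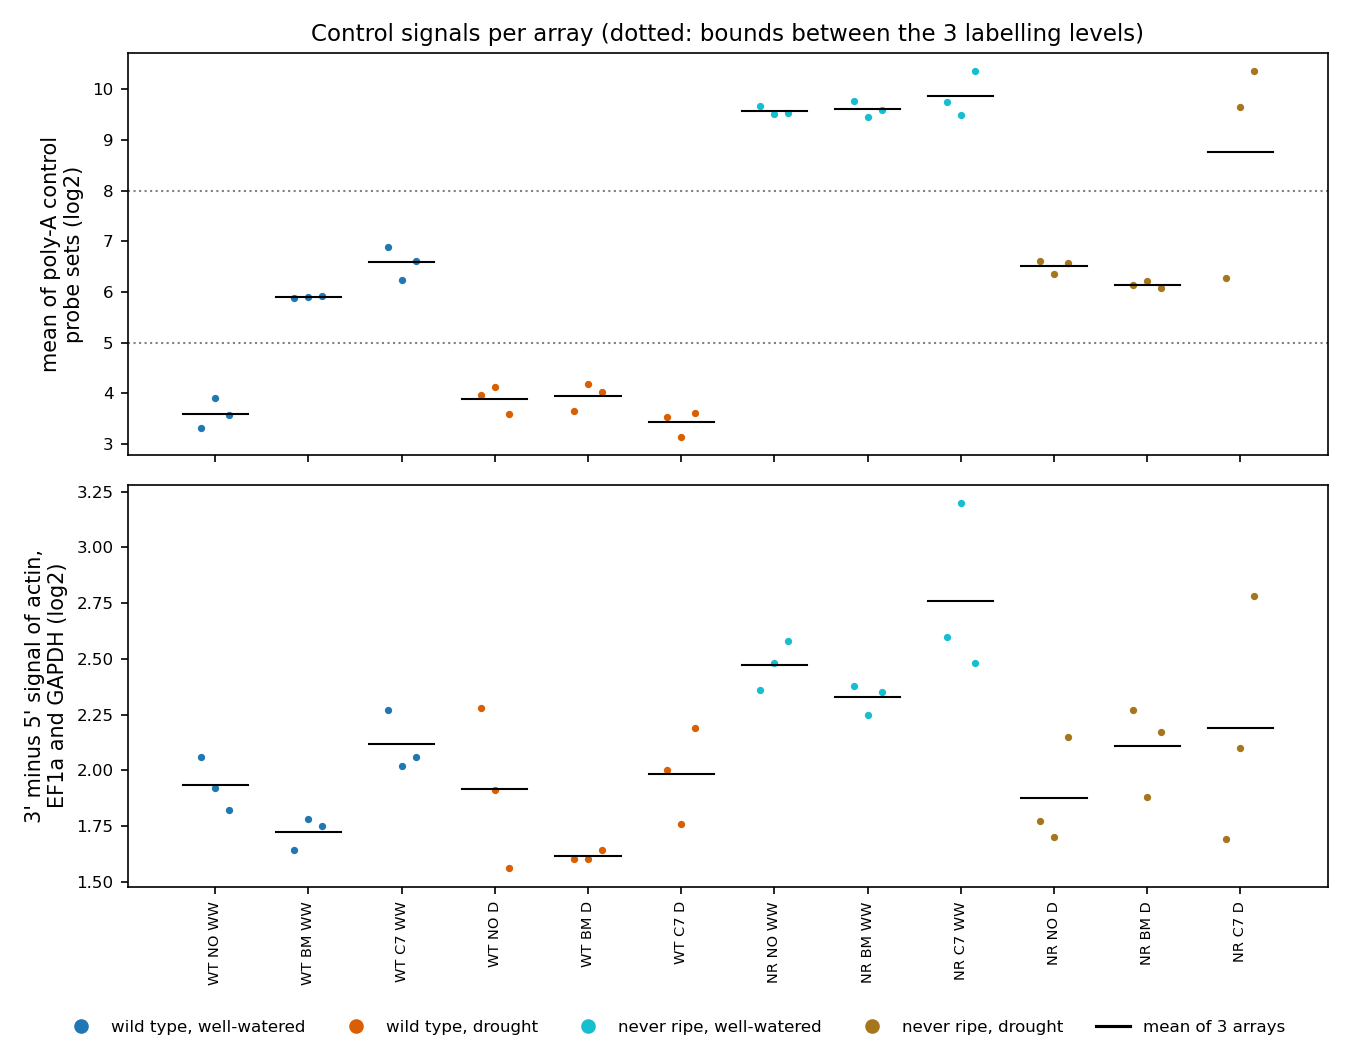
The upper panel plots the mean of the poly-A control probe sets and the lower panel the 3' minus 5' signal of actin, EF1a and GAPDH, both in log2 units, for each array (points) of the 12 groups, with lines at the mean of 3 arrays and dotted bounds at 5 and 8 between labelling levels. The well-watered NR groups averaged 9.56 to 9.86 in the upper panel, and the WT_NO_WW group averaged 3.60.

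Drought against full watering asks which root genes follow the water supply. Averaged over lines and inoculations (18 arrays against 18), several genes known from water deficit rose. TSW12, a lipid transfer protein gene (probe set Les.4333.1.S1_at, chromosome 10, 57837566 to 57838483), rose by 3.79 ± 0.71 (SE), or 13.8-fold (adjusted p = 0.00034, 16 of 18 drought arrays above the matched well-watered mean). The dehydrin gene TAS14 (chromosome 2, 64231292 to 64232255) rose by 1.95 ± 0.33 (adjusted p = 0.00013, 16 of 18), and LE16, another lipid transfer protein gene, by 1.86 ± 0.27 (18 of 18). Genes for the transcription factors DREB1 and AREB1 rose by 2.27 ± 0.41 and 0.92 ± 0.14. Of 14 genes of the abscisic acid and dehydration list, 6 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.13).

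Small heat shock protein genes of several cell compartments were higher under drought. ER-SHSP rose by 2.74 ± 0.52 (adjusted p = 0.00038, 16 of 18 arrays), HSP17.4 by 2.26 ± 0.56, HSP21 by 2.16 ± 0.46 and MTSHP by 2.04 ± 0.44. Of 9 heat shock and chaperone genes 6 rose, 0 fell and 3 did not pass, and 7 rose adjusted over the list alone. The list shifted up with a camera adjusted p of 0.0015, and with adjusted p = 0.69 with an estimated correlation. In the auxin list 4 of 8 genes rose and 0 fell, among them IAA7 by 1.21 ± 0.30 and IAA17 by 0.84 ± 0.18 (camera adjusted p = 0.16).

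The ethylene, jasmonate, phosphate and defence lists held genes that fell. ACO5 (chromosome 7, 32724561 to 32725779), for an enzyme of the last step of ethylene synthesis, fell by 2.89 ± 0.67 (adjusted p = 0.0019, 16 of 18 arrays), and the oxophytodienoate reductase gene opr2 (chromosome 1, 88001140 to 88004530) fell by 2.80 ± 0.38 (adjusted p = 2.3e-05, 17 of 18). The phosphate transporter gene PT2 fell by 2.20 ± 0.34, the subtilisin-like protease gene P69B by 2.06 ± 0.46, the thaumatin-like gene PR5 by 2.01 ± 0.44 and the chalcone synthase gene CHS1 by 1.79 ± 0.49. In ethylene perception and signalling 0 of 16 genes rose and 6 fell, among them the receptor genes ETR6 (−0.996 ± 0.21) and ETR4 (−0.47 ± 0.16), with a camera adjusted p of 0.29. In ethylene biosynthesis 1 of 13 rose and 3 fell. SAM1 is the 1 that rose, by 0.10 ± 0.04, and its change was −0.01 after quantile normalization. Among 15 ethylene response factors 1 rose and 4 fell, and among 10 ethylene-responsive cDNAs 2 rose and 1 fell. In the jasmonate list 2 of 22 rose and 6 fell, and in the pathogenesis list 3 of 14 rose, the chitinase gene CHI17 by 2.08 ± 0.41, and 4 fell.

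Photosynthesis genes had the second largest list median under drought, −0.69, with 0 of 9 higher and 2 lower, PsbQ by −1.02 and psaD by −0.80 (camera adjusted p = 0.23). With the 3' minus 5' signal as a covariate the median was −0.33 and 0 were lower. WRKY factors fell in 4 of 6 and phenylpropanoid genes in 5 of 11, with 1 higher. Among all 803 genes 155 rose and 178 fell, beside which the list counts are to be read. The counts higher and lower were 3 and 4 of 16 antioxidant enzymes, 1 and 3 of 9 nitrogen genes, 1 and 2 of 8 phosphate genes, and 3 and 4 of 11 iron and metal genes. They were 7 and 11 of 49 cell wall genes, 4 and 0 of 5 ribosomal protein genes, and 3 and 0 of 13 cell cycle genes. Terpenoid genes gave 3 and 3 of 17, sugar genes 4 and 7 of 23, and gibberellin, cytokinin and brassinosteroid genes 0 and 2 of 10. Adjusted over the list alone the counts differed for pathogenesis (4 and 5), jasmonate (2 and 7), WRKY (2 and 4), antioxidant (3 and 6), iron (4 and 5), cell wall (7 and 12), terpenoid (3 and 4) and sugar (6 and 7) genes. Camera adjusted p-values of all lists other than heat shock lay between 0.13 and 0.98. Median, mean and test did not share a sign in the nitrogen, phosphate, iron, gibberellin, sugar and ethylene-responsive cDNA lists, and the median of the phosphate list was 0.01 as deposited and −0.002 after quantile normalization.

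In all, 3388 probe sets differed between regimes in the average (limma), 2151 higher and 1237 lower under drought. Within non-inoculated WT, whose 6 arrays share the low labelling level, 55 passed, and an additive model with the labelling level as a term left 23. In that model 99.1% of the 3388 kept their sign and the median change kept 0.91 of its size, while the median SE went from 0.083 to 0.145, so most calls ended through a larger error. Without the 5 doubted arrays, described below, 4165 passed, but 4 of these were picked for resembling the other regime.

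The spread between arrays of a group was wide for these genes. TSW12 read 1.99 in the array labelled WT_C7_D replicate 2, against 9.21 and 10.1 in the other arrays of that group. It read 5.19 in NR_BM_D replicate 2 and 5.68 in NR_C7_D replicate 3, and 10.18 in the well-watered array NR_BM_WW replicate 2. In each of these 4 arrays the 3 closest arrays over all probe sets carried the label of the other regime. With WT_BM_D replicate 1 they make up the 5 doubted arrays.

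**Figure D2:**
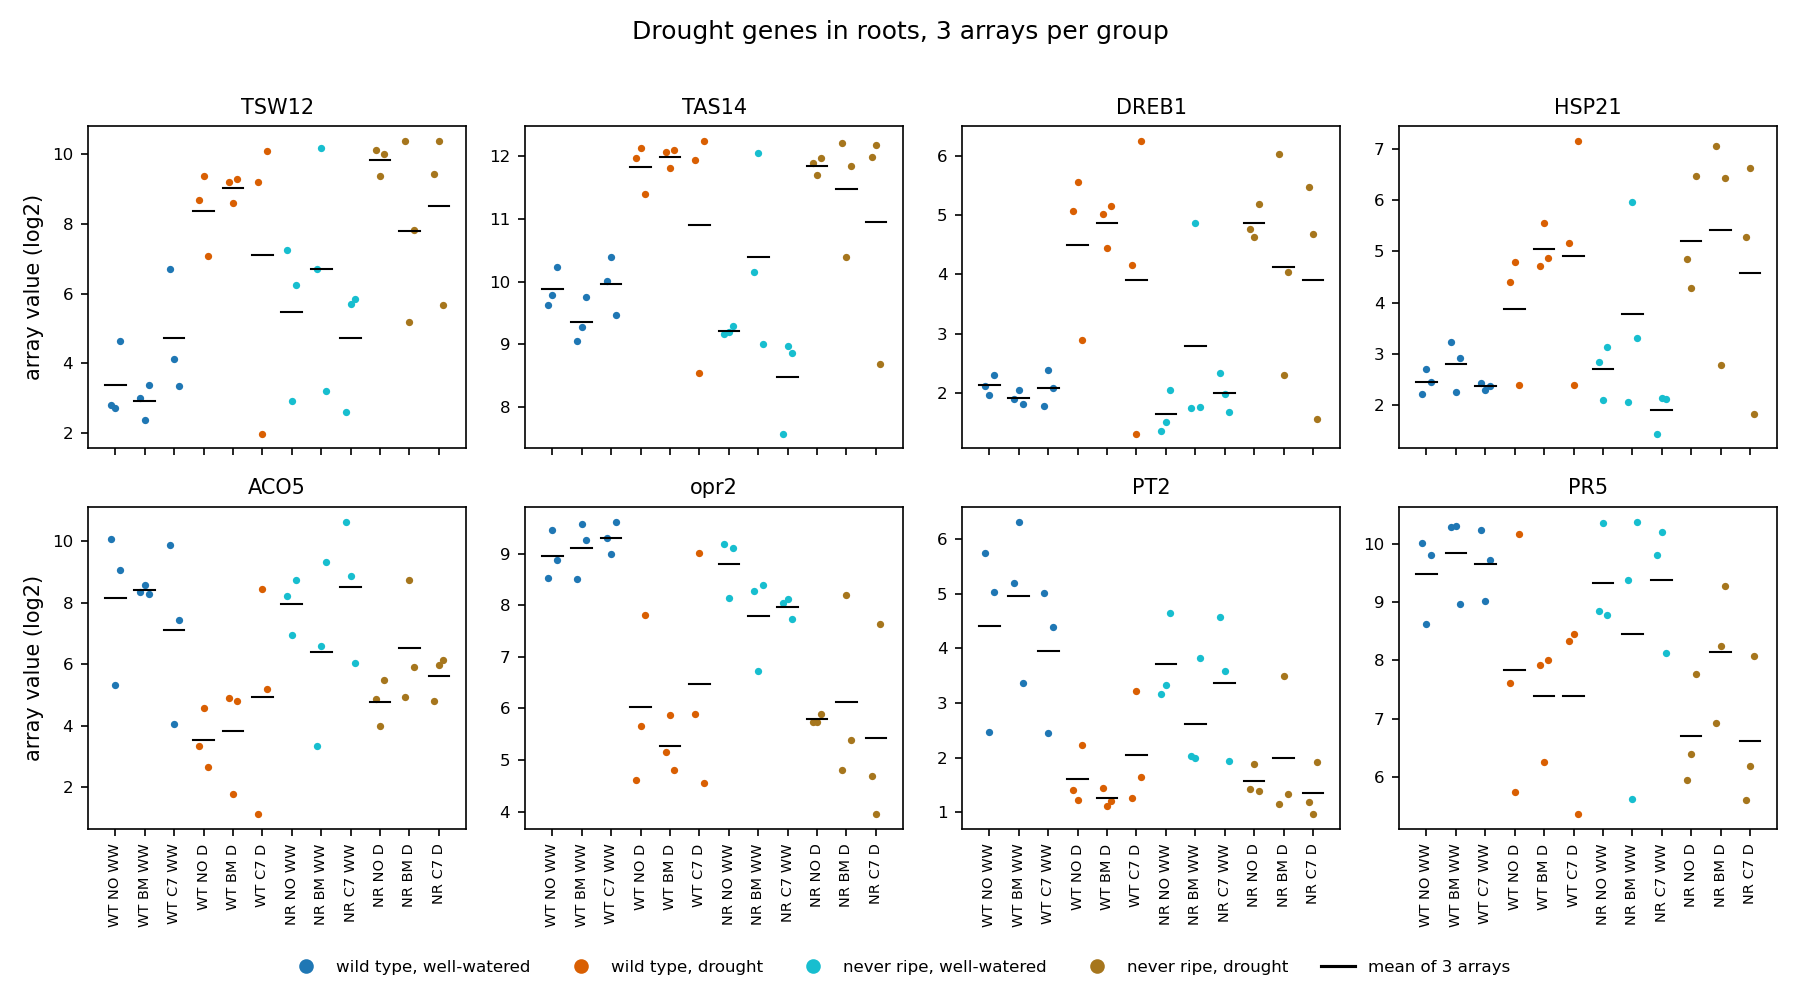
Each panel plots the array value (log2) of 1 gene in the 12 groups, with a point per array, colour for line and regime, and a line at the mean of 3 arrays. TSW12 averaged 3.40 in WT_NO_WW and 8.39 in WT_NO_D, and opr2 averaged 8.95 and 6.03, while single arrays such as WT_C7_D replicate 2 (TSW12 1.99) lay with the other regime.

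In non-inoculated WT alone (3 arrays against 3) drought raised dhbK by 0.61 ± 0.14, AN35 by 0.60 ± 0.13 and AGP-S2, a subunit of ADP-glucose pyrophosphorylase, by 0.57 ± 0.13. The ammonium transporter gene AMT1-2 fell by 1.37 ± 0.27, or 2.59-fold (adjusted p = 0.034), TDR4, a MADS-box gene, by 1.73 ± 0.38, ST3 by 0.98 ± 0.22, DXR, an enzyme of plastid isoprenoid synthesis, by 0.73 ± 0.16, and CLPP2 by 0.55 ± 0.10. In each of these genes the 3 drought arrays did not overlap the 3 well-watered ones. Photosynthesis genes had 0 of 9 past the threshold and 7 lower adjusted over the list alone (camera adjusted p = 0.0035, and adjusted p = 0.58 with an estimated correlation). Cell cycle genes had 0 of 13 past it (camera adjusted p = 0.0058, and adjusted p = 0.58 with an estimated correlation). The 55 probe sets were 31 higher and 24 lower, and without WT_NO_D replicate 1 the count was 0. Without WT_NO_WW replicate 2 it was 255, with 94 higher and 161 lower, so the balance of directions turned.

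In non-inoculated NR alone drought raised AREB1 by 1.45 ± 0.34, or 2.72-fold (adjusted p = 0.042), and the metallothionein gene LEMT1 by 0.48 ± 0.11, and ST3 fell by 1.01 ± 0.22. In the abscisic acid and dehydration list 1 of 14 rose, 0 fell and 6 rose adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation). Heat shock genes had 0 of 9 past the threshold, with a median of 2.06 (camera adjusted p = 0.00092, and adjusted p = 0.81 with an estimated correlation). There were 72 probe sets, 63 higher and 9 lower, from arrays of high and middle labelling level, so that regime and level cannot be told apart here. Leaving out 1 array brought the count down to as few as 1. With the 3' minus 5' signal as a covariate the count was 0. Across the 10038 probe sets, which are not independent, drought changes in WT and NR correlated with r = 0.63 (rho = 0.54), and 69.2% had the same sign.

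NR against WT asks what ethylene insensitivity goes with in the root. Averaged over regimes and inoculations (18 arrays labelled NR against 18 labelled WT), 8 of 17 terpenoid and carotenoid genes were lower in NR. HMGR, for the enzyme that makes mevalonate (probe set Les.4372.1.S1_at, chromosome 2, 62153180 to 62155923), fell by 0.63 ± 0.08 (adjusted p = 3.3e-06, 17 of 18 arrays), ZDS, a carotenoid desaturase gene, by 0.59 ± 0.07, the carotene hydroxylase gene CrtR-b1 by 1.04 ± 0.16 and the phytoene synthase gene PSY2 by 0.46 ± 0.14. Of 17 genes 0 were higher, 8 lower and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.13 with an estimated correlation). With the labelling level as a term the list median was −0.13 (camera adjusted p = 0.061), and HMGR was at −0.13 ± 0.20 (adjusted p = 0.91) while ZDS was at −0.64 ± 0.19 and CrtR-b1 at −1.14 ± 0.42. NCED1, which acts on carotenoid products in abscisic acid synthesis, fell by 0.56 ± 0.15, and its list of 14 had 2 higher and 3 lower.

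Some genes of heat shock proteins and of cell walls were higher in NR. HSP17.4 rose by 2.15 ± 0.56 (adjusted p = 0.0038, 16 of 18 arrays), MTSHP by 2.12 ± 0.44 and the cytosolic chaperone gene Hsp90-1 by 0.49 ± 0.06 (adjusted p = 5.3e-06, 18 of 18). Of 9 heat shock genes 4 rose, 0 fell and 5 did not pass (camera adjusted p = 0.022, and adjusted p = 0.80 with an estimated correlation). Of 49 cell wall genes 12 rose, 2 fell and 35 did not pass (camera adjusted p = 0.022, and adjusted p = 0.80 with an estimated correlation), among them the beta-galactosidase gene TBG7 (1.12 ± 0.23), LeXTH9 (1.08 ± 0.28) and the expansin gene EXP12 (0.93 ± 0.12). Both lists had the same counts adjusted over the list alone. The cell wall list had a camera adjusted p of 0.051 with the 3' minus 5' signal as a covariate and 0.11 with the labelling level as a term, where LeXTH9 was at 0.08 ± 0.70, TBG7 at 0.56 ± 0.56 and EXP12 at 0.77 ± 0.36. Among 13 cell cycle genes 4 rose, CDKB1 by 0.55 ± 0.10 and PCNA by 0.47 ± 0.09, and 1 fell (camera adjusted p = 0.11).

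Single genes that differed included the ascorbate peroxidase gene APX, higher in NR by 0.65 ± 0.06 (adjusted p = 8.6e-09) with no overlap between the lines, and BR1, higher by 1.53 ± 0.20. APX read low, with means of 3.58 in NR and 2.91 in WT without WT_BM_D replicate 1, below the array medians. With the labelling level as a term APX was at 0.60 ± 0.14 and BR1 at 0.77 ± 0.54, and no named gene passed between the lines. The translation factor gene eIF-5A1 (chromosome 3, 62144355 to 62146911) was lower by 2.16-fold, a log2 change of −1.11 ± 0.10 (adjusted p = 9.9e-09, 18 of 18 arrays). CIP1 fell by 1.51 ± 0.17, Asc-1 by 1.27 ± 0.20 and DDTFR18 by 1.19 ± 0.14. The ethylene-responsive cDNA ER24 and the fruit gene 2A11 rose by 1.58 ± 0.31 and 1.22 ± 0.28.

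The ethylene lists moved both ways or little between the lines. ETR3, the receptor gene mutated in never ripe (probe set Les.85.1.S1_at, chromosome 9, 64449938 to 64459231), was lower in NR by 1.27-fold, a log2 change of −0.35 ± 0.06 (adjusted p = 9.8e-05, 17 of 18 arrays). The mutation changes the protein, so the array level does not show which allele an array holds. Of 16 perception and signalling genes 1 rose and 5 fell, with ETR6 at −0.99 ± 0.21, EIL1 at −0.24 ± 0.05 and CTR4 at −0.26 ± 0.06, and a camera adjusted p of 0.45. The list median was −0.003 as deposited and 0.01 after quantile normalization. In ethylene biosynthesis 0 of 13 rose and 3 fell, ACS3 by 0.99 ± 0.34, ACS1A by 0.88 ± 0.23 and SAM1 by 0.14 ± 0.04. The SAM1 change was 0.001 after quantile normalization, and the list median went from −0.06 to 0.001. Of 15 ethylene response factors 1 rose, ERF-H1 by 0.98 ± 0.21, and 6 fell, with 3 lower after quantile normalization and 0 with the 3' minus 5' signal as a covariate. Of 10 ethylene-responsive cDNAs 2 rose and 0 fell.

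Among the other lists no camera test passed between the lines. In the auxin list 4 of 8 rose and 2 fell, IAA3 by 1.12 ± 0.28. Of 9 photosynthesis genes 0 rose and 3 fell, CAB5 by 1.25 ± 0.43. The median of that list was −0.34 (camera adjusted p = 0.34), and −0.82 with the 3' minus 5' signal as a covariate (camera adjusted p = 0.030, and adjusted p = 0.81 with an estimated correlation). Among all 803 genes 130 rose and 133 fell between the lines, beside which the list counts are to be read. The counts higher and lower were 0 and 0 of 14 pathogenesis genes (limma, adjusted over all probe sets), 1 and 0 of 22 jasmonate genes, 1 and 0 of 6 WRKY factors, and 0 and 1 of 11 phenylpropanoid genes. They were 2 and 2 of 16 antioxidant enzymes, 1 and 1 of 9 nitrogen genes, 0 and 1 of 8 phosphate genes, and 1 and 2 of 11 iron and metal genes. Ribosomal proteins gave 2 and 0 of 5, sugar genes 3 and 2 of 23, and gibberellin, cytokinin and brassinosteroid genes 1 and 2 of 10. Adjusted over the list alone the counts differed for jasmonate (0 and 0), antioxidant (1 and 2), cell cycle (5 and 1) and sugar (2 and 1) genes. Camera adjusted p-values outside the 3 lists above lay between 0.11 and 0.92. Median, mean and test did not share a sign in the ethylene-responsive cDNA, abscisic acid, pathogenesis, auxin, gibberellin and phenylpropanoid lists.

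In all, 3576 probe sets differed between the lines, 1771 higher and 1805 lower in NR, and after quantile normalization 2036 were higher and 1526 lower. No labelling level holds both lines under 1 regime, and an additive model with the level as a term left 6 probe sets. In that model ODD, higher in NR by 1.08 ± 0.39 as reported, had a change of −0.66. With the 3' minus 5' signal as a covariate 1154 passed, and ETR3 no longer did (−0.23, adjusted p = 0.052).

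The array labelled WT_BM_D replicate 1 counted as WT in all comparisons. At 5 probe sets without a gene name, which parted the other 35 arrays by line without overlap and by a log2 difference of 3 or more, this array lay nearer the NR mean in 5 of 5. Of 15 probe sets that parted the lines at any size it lay nearer NR in 13, and nearer WT at LesAffx.33303.1.S1_at and LesAffx.61058.1.S1_at. These were picked after their values were seen. At Les.1842.1.S1_at the other WT arrays averaged 7.43 (SD 0.16, n = 17), the NR arrays 0.89 (SD 0.21, n = 18), and this array read 0.91. At Les.5230.1.S1_at the values were 5.98, 1.09 and 1.30. Without it 3526 probe sets differed between the lines.

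**Figure D3:**
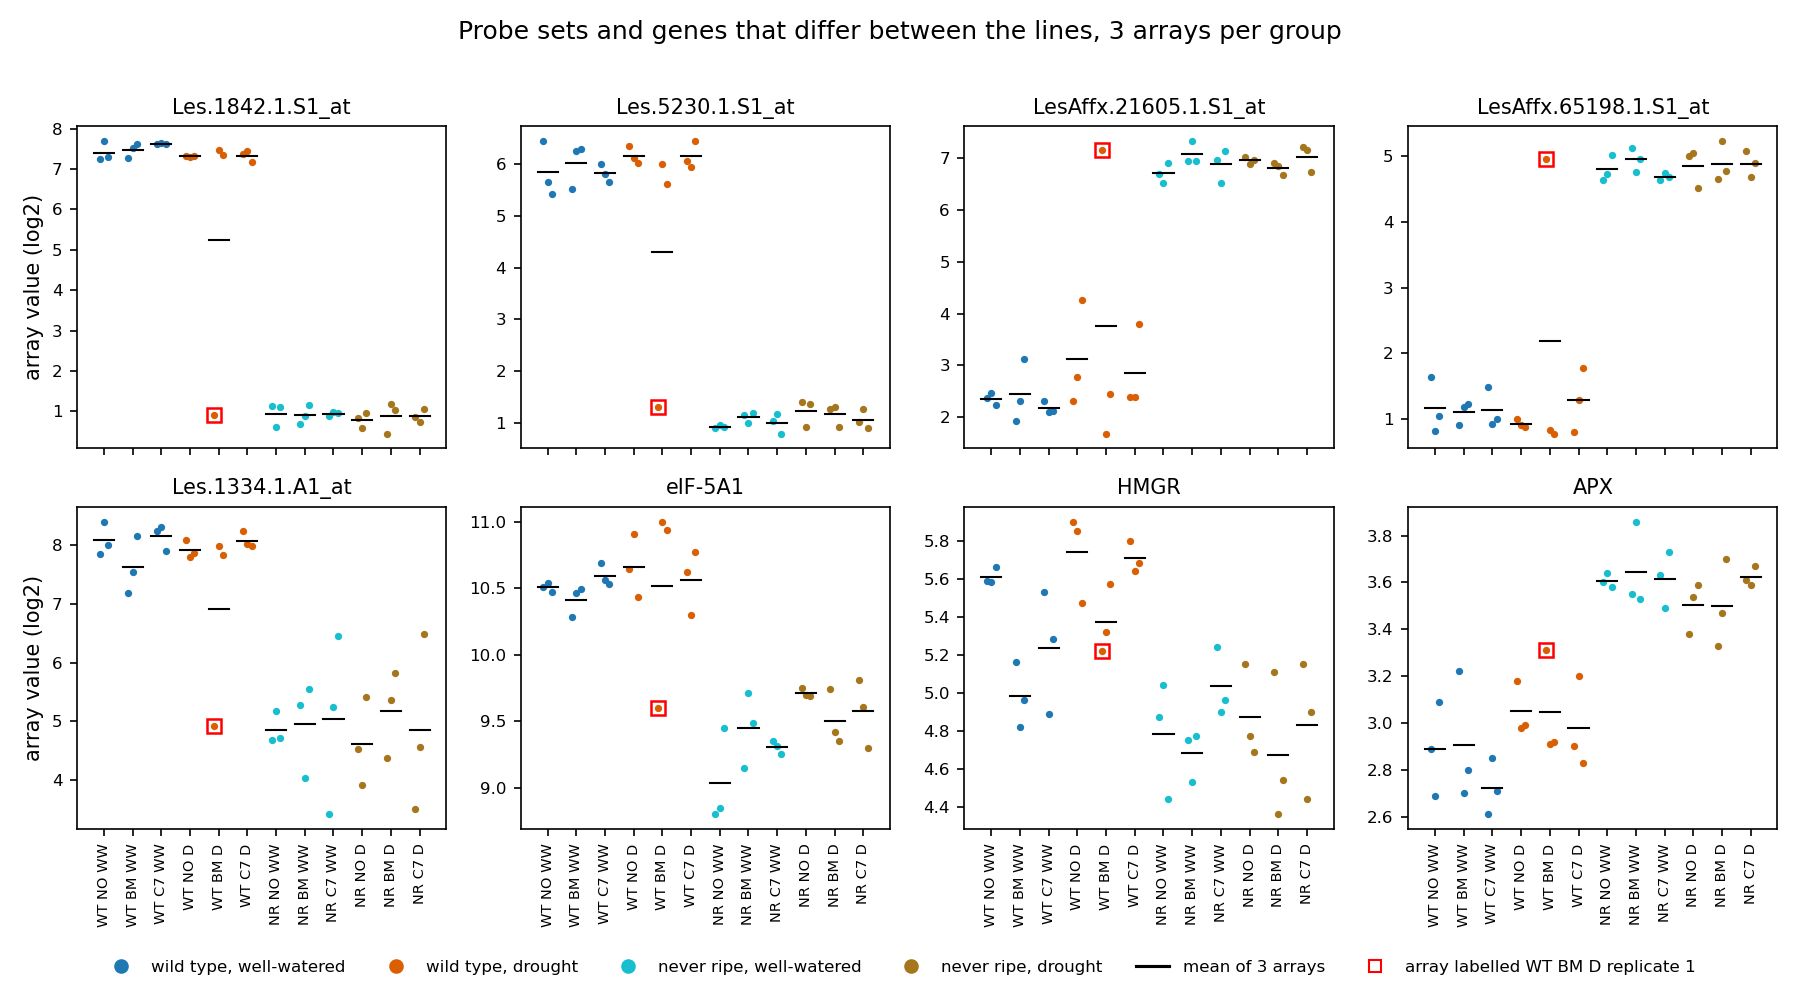
Panels plot array values (log2) of 5 unnamed probe sets and of eIF-5A1, HMGR and APX in the 12 groups, with a point per array, colour for line and regime, a line at the mean of 3 arrays and a red square at the array labelled WT_BM_D replicate 1. At Les.1842.1.S1_at that array reads 0.91, by the NR mean of 0.89, while the other WT arrays lie between 7.18 and 7.70.

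In non-inoculated well-watered plants (3 against 3) 2 of 17 terpenoid genes were lower in NR, HMGR by −0.83 ± 0.20 (adjusted p = 0.032) and ZDS by −0.66 ± 0.17 on the log2 scale. None rose and 15 did not pass, with the same counts adjusted over the list alone and a median of −0.38 (camera adjusted p = 1.8e-05, and adjusted p = 0.018 with an estimated correlation). It is the only 1 of 43 list calls, from 572 tests of lists, that held with an estimated correlation. BR1 rose by 1.98 ± 0.50, WRKYIId-2, a WRKY factor gene, by 0.80 ± 0.19 and APX by 0.72 ± 0.14, while eIF-5A1 fell by 1.48 ± 0.24 and GPAT by 0.56 ± 0.14. Photosynthesis, cell wall and cell cycle lists had 0 members past the threshold, and 2 cell cycle genes were higher adjusted over the list alone (camera adjusted p = 0.020, 0.020 and 0.049, each with adjusted p = 0.70 with an estimated correlation). There were 110 probe sets, 38 higher and 72 lower, and 53 higher and 65 lower after quantile normalization. Without WT_NO_WW replicate 3 there were 45. The NR arrays were of high and the WT arrays of low labelling level, so line and level cannot be told apart here.

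In non-inoculated plants under drought no named gene passed between the lines. The genes of lowest p were HMGR, at −0.87 ± 0.20 (adjusted p = 0.11), and ADCS, at −0.81 ± 0.19 (adjusted p = 0.16). Heat shock genes had 0 of 9 past the threshold, 1 higher adjusted over the list alone and a median of 0.96 (camera adjusted p = 0.00026, and adjusted p = 0.73 with an estimated correlation). The 8 probe sets past it, 3 higher and 5 lower, had no gene name. Among them Les.1842.1.S1_at averaged 0.79 (SD 0.20) in NR and 7.31 in WT. The NR level lies near the bottom of the value range (0.205), so the size of its change is uncertain. The NR arrays were of middle and the WT arrays of low labelling level. Across the 10038 probe sets the line difference in the well-watered and the drought regime correlated with r = 0.34 (rho = 0.32), and 62.5% had the same sign.

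Inoculation with Bacillus megaterium against none asks what this strain changes in the root. No gene passed the threshold in any line and regime or in the average (12 arrays against 12). In the average, CTR1, a kinase gene of ethylene signalling, was at −0.22 ± 0.06 and TBN1, a nuclease gene, at 0.40 ± 0.12, both with adjusted p = 0.999. Ethylene perception and signalling genes had a median of −0.12, with 0 of 16 past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 2.3e-05, and adjusted p = 0.29 with an estimated correlation). Photosynthesis genes had a median of 0.40 (camera adjusted p = 0.00019, and adjusted p = 0.75 with an estimated correlation), heat shock genes 0.49 (0.015, and adjusted p = 0.75 with an estimated correlation) and sugar genes −0.10 (0.028, and adjusted p = 0.11 with an estimated correlation), all with 0 members past it. limma gave 0 probe sets in the average, with 392 at an unadjusted p under 0.05. It gave 0 in WT_WW (651 unadjusted), WT_D (320), NR_WW (243) and NR_D (409). Chance alone gives a share of 0.05 of the 10038 probe sets at that unadjusted p, here and in the contrasts below. That is more than each of these counts but the 651.

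By line and regime the 2 genes of lowest p with Bacillus megaterium were HMGR (−0.63 ± 0.20) and TCTR2 (−0.31 ± 0.11) in well-watered WT, and CTR1 (−0.52 ± 0.12) and fsm1 (−1.64 ± 0.44) in WT under drought, where 1 of the inoculated arrays is the array labelled WT_BM_D replicate 1. They were XTH6 (−0.98 ± 0.27) and P69A (−0.54 ± 0.15) in well-watered NR, and rnalx (1.25 ± 0.41) and TBN1 (0.63 ± 0.23) in NR under drought, with adjusted p from 0.55 to 0.999. Lists called in well-watered WT were ethylene perception (down, 1.7e-05, and adjusted p = 0.14 with an estimated correlation), phenylpropanoids (up, 0.0077, and adjusted p = 0.14 with an estimated correlation), and nitrogen, photosynthesis and sugars (each 0.031, and adjusted p = 0.10, 0.89 and 0.10 with an estimated correlation). In WT under drought they were ethylene perception and photosynthesis (each 0.0046, and adjusted p = 0.74 and 0.87 with an estimated correlation) and heat shock (0.033, and adjusted p = 0.87 with an estimated correlation). In well-watered NR heat shock genes were called (median 1.08, 0.0034, and adjusted p = 0.78 with an estimated correlation). That call rests on NR_BM_WW replicate 2, which lies with drought arrays, and without the doubted arrays the median was 0.05 (adjusted p = 0.45). The photosynthesis call in well-watered WT had an adjusted p of 0.053 without them, at the same median, since its groups hold none of them. In WT under drought the ethylene perception call had a camera adjusted p of 0.047 without the doubted arrays. Without the nearly identical arrays as well it was 0.051. In well-watered WT the inoculated groups were of middle and the control of low labelling level, so inoculation and level cannot be told apart there, while WT_D and NR_WW groups each share 1 level.

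Inoculation with Enterobacter C7 against none asks the same of this strain. In well-watered WT the genes of lowest p were MAPK10, a MAP kinase gene, at 0.35 ± 0.10 (adjusted p = 0.37) and app2 at 0.31 ± 0.11, and in WT under drought AMT1-2 at 0.89 ± 0.27 and fsm1 at −1.41 ± 0.44. In NR they were MFP1 (0.43 ± 0.14) and the expansin gene EXPA3 (0.60 ± 0.20) when well-watered, and the gene TIP (−1.10 ± 0.32) and CS2 (0.39 ± 0.14) under drought. In the average they were TCTR1v (0.21 ± 0.07) and hqt (−0.37 ± 0.12), both with adjusted p = 0.95. Called lists were ethylene perception in well-watered WT (median 0.13, camera adjusted p = 0.0076, and adjusted p = 0.71 with an estimated correlation), photosynthesis in WT under drought (median 1.08, 0.0020, and adjusted p = 0.66 with an estimated correlation) and cell cycle in well-watered NR (median 0.33, 0.0033, and adjusted p = 0.54 with an estimated correlation), all with 0 members past the threshold. WT_C7_D replicate 2 lies with well-watered arrays, and without the doubted arrays the photosynthesis median was 1.28 (adjusted p = 0.0051).

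With Enterobacter C7, 4 probe sets passed in well-watered WT, all without a gene name and named here after their values were seen. LesAffx.66410.1.S1_at fell by 2.62 ± 0.44, LesAffx.3698.2.A1_at by 1.34 ± 0.23 and LesAffx.18735.1.S1_at by 1.27 ± 0.23, and LesAffx.39187.1.S1_at rose by 0.84 ± 0.16. In NR under drought Les.1999.1.A1_at fell by 1.44 ± 0.22, and in the average LesAffx.3299.1.S1_at rose by 0.35 ± 0.06. LesAffx.3299.1.S1_at averaged 1.60 with C7 and 1.25 without, near the bottom of the value range (0.205), and the arrays overlapped. The size of its change is therefore uncertain. limma gave 0 in WT_D (354 at an unadjusted p under 0.05) and NR_WW (506). A fit to the groups of the contrast alone left 0 in well-watered WT and in NR under drought. Of the NR_C7_D arrays 2 were of high and 1 of middle labelling level, while NR_NO_D and NR_BM_D were all middle, so both strain comparisons with NR_C7_D are partly confounded with the level. NR_C7_D replicate 3 is also a doubted array and nearly identical to NR_C7_WW replicate 3. Without it the count for C7 in NR under drought was 0.

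Enterobacter C7 against Bacillus megaterium asks whether the strains differ. In well-watered WT, ethylene perception and signalling genes had a median of 0.33 higher with C7, with 0 of 16 past the threshold and 10 higher adjusted over the list alone (camera adjusted p = 2.2e-07, and adjusted p = 0.22 with an estimated correlation). TCTR2 was at 0.52 ± 0.11 (adjusted p = 0.052) and app2 at 0.49 ± 0.11 (adjusted p = 0.063). Photosynthesis genes had a median of −1.09 (0.0017, and adjusted p = 0.67 with an estimated correlation) and phenylpropanoid genes −0.27 (0.022, and adjusted p = 0.44 with an estimated correlation). The arrays of this contrast also differ in the 3' minus 5' signal, at 1.64 to 1.78 in WT_BM_WW and 2.02 to 2.27 in WT_C7_WW. No fit with that signal as a covariate was made here, so strain and RNA quality cannot be told apart in well-watered WT. In well-watered NR the medians were −1.87 for heat shock (0.0017, and adjusted p = 0.88 with an estimated correlation), 0.47 for cell cycle (0.00078, and adjusted p = 0.73 with an estimated correlation) and 0.18 for cell wall genes (0.0064, and adjusted p = 0.88 with an estimated correlation). NR_BM_WW replicate 2 lies with drought arrays and NR_C7_WW replicate 3 is nearly identical to a drought-labelled array. Without the doubted arrays the heat shock median was −0.62 and the cell wall median 0.25 (both adjusted p = 0.068), and without the nearly identical arrays as well they were −0.48 (0.17) and 0.27 (0.15). In the average, ethylene perception genes had a median of 0.11, with 2 of 16 higher adjusted over the list alone (1.3e-05, and adjusted p = 0.37 with an estimated correlation), photosynthesis genes −0.48 (0.0047, adjusted p = 0.74 with an estimated correlation, and 0.15 without the doubted arrays) and phenylpropanoid genes −0.16 (0.016, and adjusted p = 0.37 with an estimated correlation).

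Between the strains the genes of lowest p elsewhere were ATG6 (−0.85 ± 0.23) and MADS1 (0.60 ± 0.18) in WT under drought, Eli3 (−2.16 ± 0.56) and ACS8 (1.26 ± 0.38) in well-watered NR, GolS-1 (−0.44 ± 0.15) and XTH7 (−0.46 ± 0.16) in NR under drought, and TBN1 (−0.46 ± 0.12) and IMP1 (0.23 ± 0.06) in the average (both adjusted p = 0.31). In well-watered WT 4 unnamed probe sets, named after their values were seen, were higher with C7. They were Les.1328.1.A1_at (0.91 ± 0.14), LesAffx.39187.1.S1_at (0.90 ± 0.16), Les.5779.1.S1_at (0.62 ± 0.11) and Les.5604.1.S1_at (0.48 ± 0.09). Les.1859.3.S1_at was lower by −1.79 ± 0.31 in well-watered NR and Les.1999.1.A1_at by −1.70 ± 0.22 in NR under drought. In NR under drought both sides hold a doubted array, NR_C7_D replicate 3 and NR_BM_D replicate 2. limma gave 0 in WT_D (902 at an unadjusted p under 0.05) and in the average (1111). A fit to the groups of the contrast alone left 0 in well-watered WT and in both NR contrasts, and leaving out 1 array gave 0 to 459 in well-watered WT and 0 to 2 in well-watered NR. Array weights moved the count in well-watered WT to 1330 and in WT under drought to 416.

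Interactions ask whether an effect depends on line or regime. ZDS had the lowest p for line by drought, at 0.60 ± 0.14 (adjusted p = 0.069), followed by CLPP2 at 0.33 ± 0.08 (adjusted p = 0.11). For line by BM the genes of lowest p were P69A (−0.48 ± 0.15) and CTR1 (0.37 ± 0.12), for drought by BM CCH (0.34 ± 0.10) and cel5 (1.21 ± 0.40), for line by C7 lin5 (−0.46 ± 0.15) and EXP12 (0.85 ± 0.30), and for drought by C7 rnalx (1.53 ± 0.41) and LeMA-1 (−0.27 ± 0.07). Lists called were photosynthesis (median 1.16, camera adjusted p = 0.00022, and adjusted p = 0.67 with an estimated correlation) and cell cycle (−0.22, 0.0034, and adjusted p = 0.67 with an estimated correlation) for line by drought. For line by BM they were ethylene perception (0.16, 9.0e-05, and adjusted p = 0.39 with an estimated correlation) and phenylpropanoids (−0.28, 0.0052, and adjusted p = 0.37 with an estimated correlation), and for drought by C7 cell cycle (−0.19, 0.0080, and adjusted p = 0.59 with an estimated correlation). limma gave 0 probe sets for line by drought (1126 at an unadjusted p under 0.05, smallest adjusted p = 0.0504), line by BM (313), drought by BM (271), line by C7 (263) and drought by C7 (453). For line by drought the count was 6 after quantile normalization and 595 with array weights.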

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

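The tests on the array labelled WT_BM_D replicate 1 were chosen after the results were seen, and so were the bounds between labelling levels, the leave-one-out spread of the drought test and the choice of markers without the low level. For the line average a condition on the size of change was added to the bound after the first values were known. The rules for NR RNA under a WT label and for the labelling level of that array were set when the marker values were known, and a first rule for that level, which asked for all markers in all arrays, was not met.

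The 3576 probe sets between lines and 3388 between regimes come from groups that also differ in labelling level and in the 3' minus 5' signal of control genes. For drought, the labelling level as the whole cause is argued against by non-inoculated WT, which shares 1 level. There 91.7% of 2529 probe sets called from the other 30 arrays had the same sign, against 73.4% of all probe sets. The share of the 2529 was 88.2% to 91.7% with 1 of the 6 arrays left out, with a median ratio of changes of 1.01. The highest other split, which keeps part of the drought difference, gave 84.1%. RNA quality as measured by the 3' minus 5' signal is not enough for the drought average either, since 58.4% of its calls kept threshold and sign with the signal as a covariate (ratio 0.94). For the lines the covariate kept 27.9% (ratio 0.79) and the labelling level as a term kept 0.168%, which met the bound written for a batch as the cause, but the changes kept 0.84 of their size while the median SE went from 0.071 to 0.188, so the calls ended mostly through a larger error, and line and labelling level cannot be told apart.

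The array labelled WT_BM_D replicate 1 lies with NR at 5 of 5 probe sets that part the other 35 arrays by line, and its closest array over all probe sets is NR_NO_D replicate 1 (root mean square difference 0.288). A mixture of RNA of both lines is argued against, since at 0 of the 3 probe sets bright in WT does it lie above the highest NR array. With 5 markers chosen again without any array of the low labelling level, 5 of the 11 other low arrays lay nearer WT at all of them and the rest at 4, while this array did so at 0, which argues against a labelling level that all of them share. NR RNA under a WT label is a hypothesis consistent with the 5 of 5, found and tested on the same data, and no genotype was read.

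The arrays labelled NR_C7_WW replicate 3 and NR_C7_D replicate 3 are nearly identical, with a root mean square difference of 0.223 over all probe sets, against 0.288 for the next closest pair and 0.354 for the closest pair within a group. Over the 500 probe sets most variable within groups their difference was 49.8% of the smallest among the other pairs (0.338 against 0.679). This is in line with 1 RNA hybridised under 2 labels, but the pair was picked for its closeness and the bound of 50 was met narrowly. Which label would be right was not tested.

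Several gene lists were called in interactions with the preset correlation of camera and not with an estimated one. Ethylene perception in line by BM had an adjusted p of 9.03e-05 (adjusted p = 0.39 with an estimated correlation). Phenylpropanoids in line by BM had 0.0052 (adjusted p = 0.37 with an estimated correlation). Cell cycle had 0.0080 in drought by C7 (adjusted p = 0.59 with an estimated correlation) and 0.0034 in line by drought (adjusted p = 0.67 with an estimated correlation). Photosynthesis in line by drought had 0.000217 (adjusted p = 0.67 with an estimated correlation). Each of these interactions holds groups of well-watered WT, where inoculation and labelling level cannot be told apart. Poly-A controls averaged 9.68 in well-watered NR, 7.14 in NR under drought and 5.36 in well-watered WT, above the 3.60 of WT_NO_WW. Groups of 3 were not tested for outlying samples.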

How the results depend on the processing

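Quantile normalization gave 6 probe sets for line by drought, against 0, and turned the sign of SAM1 to 0.001 between lines and −0.005 under drought. Dropping the dimmest probe sets gave 0 for the C7 average, 17 for C7 against BM in WT_WW, 2 in NR_WW and 6 for line by drought. The replicate block, which assumes pairing by number, gave 3 for C7 against BM in NR_WW, 14 for drought in non-inoculated WT and 12 for line by drought.

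Array weights moved most single contrasts. For BM they gave 4 in WT_WW and 2 in WT_D. For C7 they gave 18 in WT_WW, 5 in WT_D, 1 in NR_WW and 3 in NR_D. For C7 against BM they gave 1330 in WT_WW, 416 in WT_D, 2 in NR_WW and 6 in NR_D. Between lines without inoculation they gave 559 well-watered and 119 under drought, and for drought 1493 in WT and 1675 in NR. Interactions had 6 for line by BM, 1 for line by C7, 5 for drought by C7 and 595 for line by drought. The cause was not tested.

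With only the groups of the contrast in the fit the count was 0 for C7 in WT_WW and NR_D, 0 for C7 against BM in WT_WW, NR_WW and NR_D, 37 between lines well-watered, 0 for drought in WT and 345 for drought in NR. With an estimated correlation 1 of 43 gene list calls held.

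The following settings were chosen after seeing the data. Without the 2 nearly identical arrays drought gave 119 in WT and 231 in NR, and line by drought 32. Without the 5 doubted arrays the C7 average gave 0, the lines under drought 19, drought 613 in WT and 508 in NR, and line by drought 6. The arrays removed in both settings are all in inoculated groups. The drought and line contrasts without inoculation therefore kept their changes, and their counts moved through the pooled spread. The 3' minus 5' covariate gave 47 between lines well-watered, 1154 in the line average, 92 for drought in WT and 0 in NR, and the ETR3 change was −0.234 (adjusted p = 0.052). The labelling batch as a random block gave 17 for drought in NR. The additive model gave 0 for the C7 average without the batch term. With the term it gave 0 for the C7 average, 6 for the line average and 23 for the drought average, ETR3 was −0.388 (adjusted p = 0.68), and between lines ODD turned to −0.664, AMT1-2 to 0.044 and CCH to 0.121. Of the 30 list calls in inoculation contrasts and interactions, 25 held without the 5 doubted arrays and 24 without these and the 2 nearly identical arrays. Calls in well-watered WT compare groups with none of these arrays, so their medians could not change and their holding is no test. With an estimated correlation the lowest camera adjusted p without the doubted arrays was 0.079.

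Leaving out 1 array at a time leaves 2 arrays in an arm, and the fit pools the spread. The line average ranged from 3220 to 3774 and the drought average from 2969 to 3750. Drought in non-inoculated WT ranged from 0 to 255, with 5, 255 (94 higher, 161 lower) and 1 without WT_NO_WW replicates 1, 2 and 3, and 0, 0 and 220 without WT_NO_D replicates 1, 2 and 3. Drought in non-inoculated NR ranged from 1 to 69, with 19, 6 and 8 without NR_NO_WW replicates 1, 2 and 3, and 2 and 1 without NR_NO_D replicates 1 and 2. The lines well-watered ranged from 45 to 151, with 60 and 45 without WT_NO_WW replicates 1 and 3, 61 and 72 without NR_NO_WW replicates 1 and 2. The lines under drought ranged from 4 to 7, with 4 without WT_NO_D replicate 1 or NR_NO_D replicate 2, and 5 without NR_NO_D replicate 1. The causes were not tested.

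For BM in WT_WW the range was 0 to 3, with 1 without WT_NO_WW replicate 1 or 3 and 3 without WT_BM_WW replicate 3. For C7 in WT_WW it was 0 to 31, with 2 and 0 without WT_NO_WW replicates 1 and 3, and 0, 31 and 0 without WT_C7_WW replicates 1, 2 and 3. For C7 in NR_WW it was 0 to 1, with 1 without NR_NO_WW replicate 3 or NR_C7_WW replicate 3. For C7 in NR_D it was 0 to 4, with 0 without NR_NO_D replicate 1 or NR_C7_D replicates 2 and 3, and 4 without NR_C7_D replicate 1. The C7 average ranged from 0 to 1, with 0 without WT_NO_WW replicate 2, NR_C7_WW replicate 1 or NR_NO_D replicate 3.

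For C7 against BM the range in WT_WW was 0 to 459, with 1, 0 and 459 without WT_BM_WW replicates 1, 2 and 3, and 1, 15 and 1 without WT_C7_WW replicates 1, 2 and 3. In WT_D it was 0 to 1 (WT_C7_D replicate 2). In NR_WW it was 0 to 2, with 2 without NR_C7_WW replicate 3 and 0 without any of the others. In NR_D it was 1 to 2 (NR_C7_D replicate 3). The average ranged from 0 to 4, with 2, 4 and 3 without WT_BM_WW replicate 3, WT_C7_WW replicate 2 and NR_C7_D replicate 1. Drought by C7 ranged from 0 to 1 (WT_NO_D replicate 3). Line by drought ranged from 0 to 33, with 33 without WT_BM_WW replicate 3, 25 without WT_C7_D replicate 2 and 22 without NR_C7_D replicate 3. It gave 13 and 2 without WT_NO_WW replicates 1 and 2, 14 and 6 without WT_C7_WW replicates 1 and 2, 8 without WT_NO_D replicate 3, 7 and 12 without NR_C7_WW replicates 2 and 3, 3 and 12 without NR_BM_D replicates 1 and 3, and 4 and 1 without NR_C7_D replicates 1 and 2.

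Of 172 gene calls 165 stayed after quantile normalization, 161 with the replicate block, 170 with array weights and 137 in every fit with 1 array left out. Only 156 of the 172 could be tested with the dimmest probe sets dropped, and these 156 stayed. Later settings kept 107 with the 3' minus 5' covariate and 150 with the batch as a random block, and 0 of 154 with the batch term. All groups but NR_C7_D lie within a single labelling level, and the estimated correlation within a batch was 0.03. The random block could therefore adjust little for the level, and the 150 do not speak against it.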

Other observations

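In the additive model with the labelling level only 6 probe sets still differed between the lines, all without a gene name and picked here after their values were seen. They were Les.1842.1.S1_at (−6.31), Les.5230.1.S1_at (−4.73), LesAffx.21605.1.S1_at (4.10), LesAffx.65198.1.S1_at (3.80), Les.5253.1.S1_at (−2.87) and Les.4295.1.S1_at (0.81). Les.1842.1.S1_at and Les.5230.1.S1_at in NR and LesAffx.65198.1.S1_at in WT read near the bottom of the value range, so the sizes of their changes are uncertain. Of the 23 that still differed between regimes 3 have a gene, ST3 (−0.91 ± 0.17), AN35 (0.39 ± 0.09) and ltpg1 (1.87 ± 0.38).

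Counts were set beside counts from random regroupings of the same arrays. Of 100 splits, the real one included, 1 had as many probe sets as the line average (3576, highest other 1310) and 1 as many as the drought average (3388, highest other 1362). For the C7 average 7 of 100 had as many as the real 1 (highest other 187). For the BM average and for C7 against BM 100 of 100 had as many as the real 0 (highest other 47 and 153). Every split has a count of 0 or more, so for a real 0 this share was fixed in advance and tests nothing. The interactions had 100 of 100 for a real 0, with a highest other of 657 for drought by BM, 150 for drought by C7, 65 for line by BM, 1 for line by C7 and 1 for line by drought. In several of these contrasts the highest random split called many times more probe sets than the real grouping. The cause was not tested.

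For 3 arrays against 3 the 10 splits are too few for a share under 0.05, and for a real 0 all 10 have as many by definition. Between lines the real count was 110 well-watered (highest other 1) and 8 under drought (highest other 0), and for drought 55 in WT (highest other 1) and 72 in NR (highest other 0), each reached by 1 split. For C7 it was 4 in WT_WW (1 split, highest other 0) and 1 in NR_D (2 splits, highest other 1), and 0 in WT_D (10 splits, highest other 186) and NR_WW (10 splits, highest other 0). For C7 against BM it was 4 in WT_WW (1 split, highest other 2), 0 in WT_D (10 splits, highest other 10), 1 in NR_WW (1 split, highest other 0) and 1 in NR_D (2 splits, highest other 140). For BM it was 0 in WT_WW (10 splits, highest other 236), WT_D (10 splits, highest other 0), NR_WW (10 splits, highest other 1) and NR_D (10 splits, highest other 0). The cause of the splits with 236, 186 and 140 was not tested.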
